A study of Homo sapiens with 8 samples.

How the data were processed

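RNA from A498 cells was measured on Illumina BeadChip expression arrays with biotin-labelled cRNA, 1 array per culture: 3 control cultures in medium, 3 with *E. coli* 83972 and 2 with *E. coli* CFT073, all after 4 h. The deposited values are linear processed probe intensities, 1 column per array, for 48803 probes; the authors' background correction and normalization are not given in the sources used here. In the values, 26912 probes lay at or below 13.4 on all 8 arrays and 16143 lay above it on all 8, so 13.4 was taken as a floor set by the authors (tolerance 0.0001). On 83972 arrays 2 and 3 and on both CFT073 arrays, 683 to 1909 values lay just below that floor. No array pair held identical values. Each array had its median at the floor, and 18031 to 19446 probes above it; the number of arrays, not a count of molecules, sets the precision.

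Intensities were put on the scale log2(intensity + 16), so fold changes of dim genes are understated, and a gene at the floor in all arrays of the lower group is given as "at least" its ratio to the floor. The array medians were equal, so by a rule set beforehand no further normalization was applied. They were equal only because each lay at the floor, so the rule could not see a difference in level. On the genes above the floor on all arrays, the log2 median ran from 8.42 (control array 2) to 8.54 (CFT073 array 1). This spread is wider than the rule's limit, and the median was higher on each infected array than on each control array. Quantile normalization stands among the alternatives. Probes with exactly 1 gene symbol in the platform's annotation were used, 28098 of 48803; 13 with several symbols and 20692 without one were left out of the gene tests. Symbols were compared with the current human gene table through their gene ID, which found 28059 of the IDs and not 39, and changed 0 symbols. Each of 18852 genes was represented by its probe with the highest mean over the 8 arrays. The 6450 genes at the floor on every array hold no variation and were left out of the fit, a step added after the floor was seen and a departure from the plan, which had no filter; the counts with those genes kept are printed beside the others. This left 12402 genes.

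All 8 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, residual degrees of freedom 5, prior degrees of freedom 3.09). The 3 contrasts were 83972 minus control, CFT073 minus control and CFT073 minus 83972, tested with the two-sided moderated test of limma and adjusted by Benjamini-Hochberg over the 12402 genes of a contrast, with a threshold of 0.05. A gene "rose", "fell" or is "called" where it passed. The 2 infections share their control arrays, so their agreement was set beside 100 simulations of unchanged groups against shared controls with the residual spread of each gene.

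The gene lists, their tests, the threshold, the rule for named genes and most of the other settings to try were chosen before the data were examined. The 35 lists covered cytokines and chemokines, NF-kB targets, toll-like receptor signalling, interferon-stimulated genes, immediate early genes, MAP kinase regulators, growth factors, RNA polymerase II subunits, RNA polymerase I and III subunits, general transcription factors, Mediator, ZNF genes, histones, ribosomal proteins, oxidative phosphorylation, proteasome, metallothioneins, hypoxia, unfolded protein response, heat shock, NRF2, p53, apoptosis, G1/S, G2/M, cholesterol synthesis, antimicrobial genes, junctions, TGF-beta targets, G protein-coupled receptor signalling, regulators of cytokine receptors, epithelial, leukocyte, and endothelial and fibroblast markers, and constitutive reference genes. Each list was tested with limma's camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the 35 lists of a contrast). Beside it stood camera with a correlation estimated from these arrays, in which none of the lists passed, and fry, which tests whether a list moves one way without comparing it with other genes. Counts per list are given over all genes tested and adjusted over the list alone. Some genes stand in several lists.

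Named genes were, for each infection against control, the 8 largest rises and the 8 largest falls among genes that passed with every array of one group beyond every array of the other, and the 5 of each between the strains. Up to 4 members with the smallest p were named per list, and CXCL8, IL6, TNFAIP3, NFKBIA, FOS, EGR1, ATF3, MYC and POLR2A whatever their values.

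The steps were tested on simulated data, with 200 genes changed by a log2 of 0.5, 1 or 2 in each contrast. Changes of 1 were recovered in 97.0% to 98.5% of the changed genes and changes of 0.5 in 71.6% to 79.1%. The changed genes were drawn only from genes well above the floor in control cells. These rates therefore hold for brighter genes and do not show how well changes of dim genes are found. Between 5.61% and 10% of the calls were false, in each contrast above the share that the threshold for the adjusted p aims at. The simulations changed far fewer genes than were called in the data. Alternatives covered quantile normalization and other centrings, pseudocounts of 1 and 64, filters on dim genes, the mean of a gene's probes or its most variable probe, fits of 2 groups alone, the replicate number as a block, a variance trend, array weights, stricter thresholds and leaving out each array in turn. The 5 alternatives about the floor and scaling were added after the values were seen. Figures were drawn with matplotlib 3.10.9.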

Results

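Transcript levels were measured in A498 cells, an established human kidney carcinoma cell line that serves as a model of the renal epithelium. The cells were kept for 4 h in serum-free medium alone or with 1 of 2 *Escherichia coli* strains. Strain 83972 is carried in the urinary tract without symptoms, and CFT073 is a virulent strain from a kidney infection. There were 3 arrays of control cells, 3 of cells with 83972 and 2 of cells with CFT073, described with the series as biological replicates. Each Illumina BeadChip array, read with biotin-labelled cRNA, gave an intensity for 48803 probes, and 18031 to 19446 of them (36.9% to 39.8%) lay above a common lowest intensity of 13.4, called the floor here. The median intensity of the probes above the floor on all arrays ran from 227 to 252. Replicates were close, with a median standard deviation per gene of 0.08 on the log2 scale in each of the 3 groups. Pearson's r across probes was 0.994 to 0.996 between arrays of one group and 0.968 to 0.990 between arrays of different groups, and probes are not independent replicates. The number of arrays limits the precision, most of all for CFT073. Log2 fold changes are given with their standard error (SE), with n = 3 control, n = 3 83972 and n = 2 CFT073 arrays throughout, and folds are ratios of geometric mean intensities.

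The first comparison, 83972 against control cells, asked which transcripts change in renal cells exposed to a strain that causes no symptoms. Its largest rises were in transcripts of the inflammatory response. CCL2, a chemokine that attracts monocytes, was 25.3-fold higher (log2 4.64 ± 0.10 SE, adjusted p = 1.58e-07), and TNFAIP3, a ubiquitin-editing enzyme that restrains NF-kB signalling, was 22.1-fold higher (4.40 ± 0.08, adjusted p = 9.48e-08). IL6, a cytokine that drives fever and the acute phase response, was 15.5-fold higher (3.92 ± 0.12, adjusted p = 6.15e-07), and CXCL8, a chemokine that attracts neutrophils, rose by 3.61 ± 0.08 on the log2 scale (adjusted p = 1.58e-07). The CXCL8 probe was at 90.7% to 100% of the highest intensity on each 83972 array, where a saturated signal understates the change, and a second CXCL8 probe showed 4.34. FOS, a subunit of the growth factor-induced transcription factor AP-1, fell by 2.44 ± 0.14 on the log2 scale (adjusted p = 1.17e-05). Of 12402 genes tested, 2201 rose and 1721 fell, together 31.6%.

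The other largest rises included CCL20, a chemokine for lymphocytes and dendritic cells, by 4.44 ± 0.14. CXCL1, another neutrophil chemokine, was at the floor in all control arrays and was at least 32.5-fold higher with 83972. PTX3, a secreted molecule that recognises microbes, rose by 3.94 ± 0.11, the neutrophil chemokine CXCL2 by 3.74 ± 0.10, and TRAF1, an adaptor of tumour necrosis factor receptors, by 3.65 ± 0.14, or 1.76 by its second probe. Among the largest falls was that of HSPA6, an inducible chaperone of the HSP70 family, with a log2 fold change of -3.59 ± 0.29 (adjusted p = 7.19e-05). RNU6ATAC, a small RNA of the minor spliceosome, changed by -3.26 ± 0.14, and HSPA6 and RNU6ATAC were both near the floor with 83972. ID1 and ID2, which block basic helix-loop-helix transcription factors and respond to bone morphogenetic proteins, changed by -2.91 ± 0.09 and -2.22 ± 0.11. PPP1R3C, which directs a phosphatase to glycogen, changed by -2.73 ± 0.09, the AP-1 subunit FOSB by -2.06 ± 0.23, and RGS2, an inhibitor of G protein signalling, by -1.87 ± 0.18. NFKBIA, the inhibitor that retains NF-kB in the cytoplasm, rose by 2.80 ± 0.06. EGR1, a growth factor-induced transcription factor, changed by -1.58 ± 0.09, and MYC, a transcription factor of cell growth, rose by 1.20 ± 0.11. The stress-induced transcription factor ATF3 rose by 1.26 ± 0.19, while its second probe showed 0.18 (adjusted p = 0.427). POLR2A, the catalytic subunit of RNA polymerase II, showed -0.06 ± 0.08 (adjusted p = 0.634).

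NF-kB feedback and survival targets moved together: 28 of 29 measured genes rose, and as many when adjusted over the list alone, with a median log2 fold change of 1.36. Besides TNFAIP3, TRAF1 and NFKBIA they included VCAM1, an adhesion molecule for leukocytes, at 2.66 ± 0.06, and TNFAIP2 at 2.41 ± 0.08. The list test (camera) gave an adjusted p of 2.35e-21, and the adjusted p was 0.209 with an estimated correlation. Of 27 cytokines and chemokines, 18 rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 0.71. Their camera adjusted p was 8.9e-10, and adjusted p = 0.268 with an estimated correlation. Parts of toll-like receptor signalling shifted upward, with 12 rises and 3 falls among 27 genes in both adjustments, over all genes and adjusted over the list alone. IRAK2, a kinase of the pathway, rose by 2.73 and RIPK2, a kinase of the peptidoglycan receptors, by 1.80, while TLR5, the flagellin receptor, changed by -0.81 ± 0.07 (camera adjusted p = 0.00982, adjusted p = 0.268 with an estimated correlation).

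Feedback regulators of MAP kinases rose in 13 of 18 genes and fell in 1, also when adjusted over the list alone. DUSP10 and DUSP1, phosphatases that inactivate MAP kinases, rose by 1.70 and 1.71 (camera adjusted p = 3.51e-06, adjusted p = 0.271 with an estimated correlation). Growth factors and EGFR ligands rose in 9 of 15 genes, also when adjusted over the list alone, among them GDF15, a stress-induced cytokine, by 2.85, and HBEGF, an EGFR ligand, by 1.83. Their camera adjusted p was 0.000344, and adjusted p = 0.271 with an estimated correlation. In the unfolded protein and integrated stress response list 14 of 27 genes rose and 7 fell, also when adjusted over the list alone. CHAC1, which degrades glutathione, rose by 2.66, SESN2, a regulator of mTOR, by 2.01, and ASNS, which makes asparagine, by 1.38 (camera adjusted p = 0.00508, adjusted p = 0.271 with an estimated correlation). The 7 falls became 3 without control array 1 or 83972 array 1, and 4 without control array 2.

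Heat shock genes fell in 11 of 22 measured, also when adjusted over the list alone, with a median of -0.18. HSPA1B, an inducible HSP70, changed by -1.64, HSPA1L by -1.19 and the co-chaperone DNAJB1 by -0.76 (camera adjusted p = 1.65e-05, adjusted p = 0.282 with an estimated correlation). Subunits of oxidative phosphorylation showed small falls in 23 of 70 genes (37 adjusted over the list alone), with a median of -0.17. ATP5MC3 and ATP5MJ, parts of the ATP synthase, changed by -0.31 and -0.46 (camera adjusted p = 7.9e-07, adjusted p = 0.271 with an estimated correlation). The 23 falls became 12, 11 and 10 without control array 1, 2 or 3, and 13 and 10 without 83972 array 1 or 2. Replication-dependent histone genes fell in 7 of 32, also when adjusted over the list alone, among them H1-3 by 0.59 and H2AC6 by 0.56 on the log2 scale (camera adjusted p = 0.00203, adjusted p = 0.271 with an estimated correlation).

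The immediate early genes went both ways with 83972, with 16 rises and 8 falls among 33 (17 and 8 adjusted over the list alone) and a camera adjusted p of 0.078. FOS, FOSB, EGR1, ID1 and ID2 were among the falls, while KLF6, a zinc finger transcription factor, rose by 1.96. Interferon-stimulated genes rose in 8 of 35 and fell in 3, also when adjusted over the list alone (camera adjusted p = 0.26). IRF1, an interferon-induced transcription factor, rose by 2.71 and the pro-apoptotic XAF1 by 1.50. Without control array 1 the 8 rises became 5, and they became 4 without control array 3, 83972 array 1 or 83972 array 2.

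Over all 12402 genes tested, called or not, the 2 groups of arrays did not overlap in 47.0%, where chance gives 10% for 3 arrays against 3. With the genes at the floor on every array kept in the fit, 1704 rose and 1227 fell. The balance of rises and falls rested on the scaling of the arrays: 56.1% of the calls were rises as given here, 41.6% after quantile normalization and 44.0% with arrays centred on the probes above the floor.

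**Figure D1:**
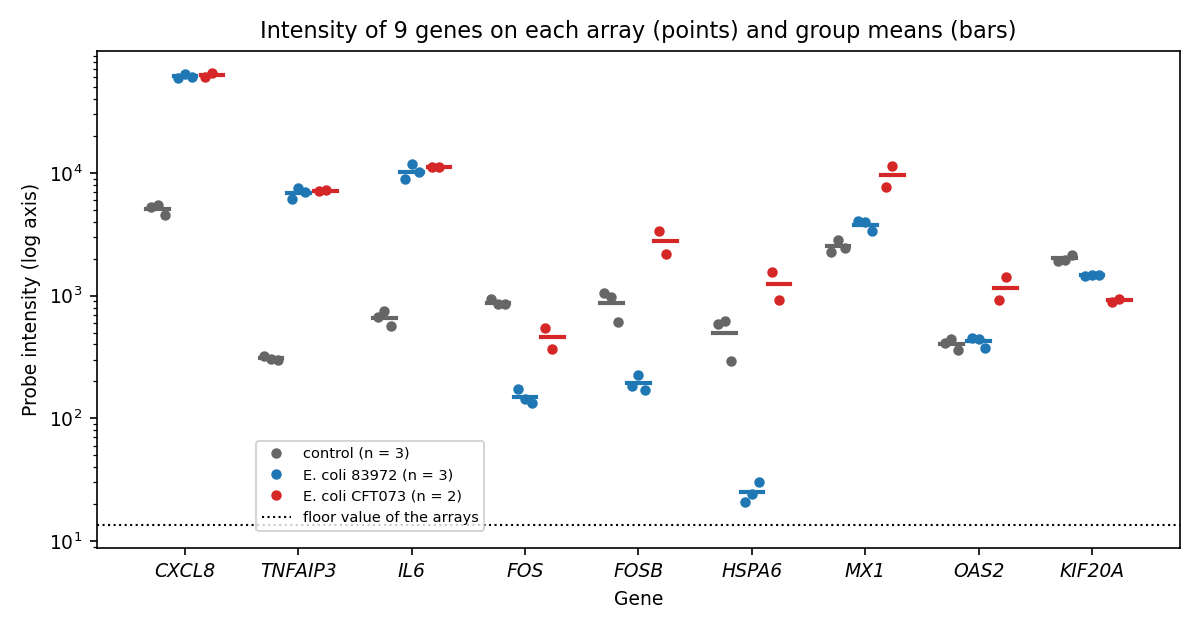
Intensity of 9 genes on each array (log axis; points are arrays, bars are group means, the dotted line is the floor of 13.4) in 3 control arrays, 3 with 83972 and 2 with CFT073. CXCL8, TNFAIP3 and IL6 were high with both strains, FOS, FOSB and HSPA6 were lowest with 83972, MX1 and OAS2 were highest with CFT073, and KIF20A was lowest with CFT073.

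The second comparison, CFT073 against control cells, asked which transcripts change with a virulent strain. CCL20 was 58.1-fold higher (log2 4.84 ± 0.15, adjusted p = 5.34e-07), CCL2 was 26.5-fold higher (4.71 ± 0.11, adjusted p = 2.94e-07), and TNFAIP3 was 23.1-fold higher (4.46 ± 0.09, adjusted p = 2.07e-07). CCL20 lay near the floor in control cells, so the size of its fold is uncertain. The virulent strain also raised 28 of 35 interferon-stimulated genes (camera adjusted p = 1.37e-10, adjusted p = 0.281 with an estimated correlation) and lowered 22 of 30 G2/M genes (2.57e-07, adjusted p = 0.236 with an estimated correlation). PTGS2, the inducible cyclooxygenase that makes prostaglandins, was 15.9-fold higher (3.89 ± 0.14, adjusted p = 9.94e-07). VAV3 was 6.51-fold lower (-2.64 ± 0.12, adjusted p = 2.11e-06). In all, 2737 genes rose and 2225 fell, together 40.0% of the genes tested.

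TRAF1 rose by 4.30 ± 0.16, PTX3 by 4.24 ± 0.13 and IL6 by 4.05 ± 0.14. ICAM4, an adhesion molecule, was at the floor in all control arrays and was at least 34.1-fold higher with CFT073. Its other probes showed log2 fold changes of 2.62 and 0.46. Falls were led, after VAV3, by PPP1R3C at -2.55 ± 0.10 and GPER1, a membrane receptor for oestrogen, at -2.43 ± 0.08, with -2.30 and -0.64 by its other probes. EEPD1, a nuclease-related gene, changed by -2.22 ± 0.16, HRCT1 by -2.11 ± 0.08, and GCNT1, which builds branches of O-linked glycans, by -2.02 ± 0.06, or -0.75 by its second probe. HSPA8, the constitutive HSP70 chaperone, changed by -2.01 ± 0.10, and PANK1, which starts coenzyme A synthesis, by -1.89 ± 0.08. CXCL8 rose by 3.63 ± 0.09, with its probe at 92.3% and 100% of the highest intensity on the CFT073 arrays, and by 4.39 by its second probe. NFKBIA rose by 2.89 ± 0.06, ATF3 by 2.13 ± 0.21, or 0.97 by its second probe, and MYC by 0.94 ± 0.12. FOS changed by -0.94 ± 0.16, EGR1 by -0.79 ± 0.10 and POLR2A by -0.43 ± 0.09 (adjusted p = 0.00653), a call that was lost without CFT073 array 1.

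All 29 measured NF-kB feedback and survival targets rose with CFT073, also when adjusted over the list alone, with a median log2 fold change of 1.92 (camera adjusted p = 1.4e-20, adjusted p = 0.203 with an estimated correlation). Of 27 cytokines and chemokines, 21 rose and 1 fell, also when adjusted over the list alone, with a median of 1.25 (camera adjusted p = 1.37e-10, adjusted p = 0.22 with an estimated correlation). The interferon-stimulated genes that rose (28 of 35, and 30 adjusted over the list alone) gave the list a median of 0.81 (camera adjusted p = 1.37e-10, adjusted p = 0.281 with an estimated correlation). They included IRF1 at 3.19, XAF1 at 2.47, the guanylate-binding protein GBP1 at 1.68 and TAP1, which carries peptides for antigen presentation, at 0.90. Toll-like receptor signalling parts rose in 15 of 27 and fell in 2, also when adjusted over the list alone, with IRAK2 at 3.22 and the kinase IKBKE at 0.91 (camera adjusted p = 0.00101, adjusted p = 0.203 with an estimated correlation). Antimicrobial and acute phase genes rose in 8 of 11, also when adjusted over the list alone, among them PTX3 and the complement component CFB at 1.47 (camera adjusted p = 0.0042, adjusted p = 0.22 with an estimated correlation). The 8 rises became 5 without control array 2 and 3 without CFT073 array 2, and the camera adjusted p was 0.0553 with the genes at the floor kept in the fit.

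Cell division genes moved the other way. Beside the 22 G2/M genes that fell, 1 rose, also when adjusted over the list alone, and the list's median was -0.45 (camera adjusted p = 2.57e-07, adjusted p = 0.236 with an estimated correlation). KIF20A and KIF11, motor proteins of mitosis, changed by -1.12 and -0.92, and CCNF, a cyclin that guides protein degradation, by -1.18. G1/S and DNA replication genes fell in 10 of 29 and rose in 2, also when adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.281 with an estimated correlation). ORC1, part of the complex that marks replication origins, changed by -1.46, while CCND1, the cyclin that starts the cell cycle, rose by 1.05. This call ended when only genes above the 75th percentile of mean level were tested (camera adjusted p = 0.0514). Subunits of oxidative phosphorylation fell in 31 of 70 (33 adjusted over the list alone), with a median of -0.19 and 16 falls without CFT073 array 2 (camera adjusted p = 1.38e-06, adjusted p = 0.281 with an estimated correlation). Heat shock genes fell in 12 of 22 and rose in 2 (13 and 2 adjusted over the list alone), among them HSPA8 and the co-chaperone BAG3 at -1.37 (camera adjusted p = 0.000141, adjusted p = 0.281 with an estimated correlation).

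Immediate early genes rose in 23 of 33 and fell in 5 (24 and 5 adjusted over the list alone), with a median of 0.84. KLF6 rose by 2.19 and the AP-1 subunit JUNB by 1.66, and ID1 changed by -1.74 (camera adjusted p = 1.32e-05, adjusted p = 0.281 with an estimated correlation). MAP kinase feedback regulators rose in 15 of 18 and fell in 1, also when adjusted over the list alone, with SPRY4, an inhibitor of receptor tyrosine kinase signalling, at 2.64, or 0.23 by its second probe (adjusted p = 0.277; camera adjusted p = 1.38e-06, adjusted p = 0.235 with an estimated correlation). Growth factors and EGFR ligands rose in 10 of 15, also when adjusted over the list alone, with HBEGF at 3.24 and BMP2, a bone morphogenetic protein, at 1.65 (camera adjusted p = 0.000141, adjusted p = 0.281 with an estimated correlation). The unfolded protein and integrated stress response list had 15 rises and 2 falls among 27 (15 and 3 adjusted over the list alone), with SESN2 at 2.43 and ASNS at 1.79 (camera adjusted p = 9.51e-05, adjusted p = 0.235 with an estimated correlation). Hypoxia-inducible genes rose in 14 of 28 and fell in 3, also when adjusted over the list alone, with VEGFA, a growth factor for vessels, at 1.40 (camera adjusted p = 0.0454, adjusted p = 0.281 with an estimated correlation). That call was lost without control array 2 or 3, any 83972 array or CFT073 array 1, with a camera adjusted p of 0.0502 without 83972 array 2.

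Over all genes tested, called or not, the 2 groups of arrays did not overlap in 58.7%, where chance gives 20% for 3 arrays against 2. With the genes at the floor on every array kept in the fit, 2223 rose and 1745 fell, and the share of rises among calls, 55.2% as given here, was 42.1% after quantile normalization and 39.7% with arrays centred on the probes above the floor.

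The responses to the 2 strains overlapped. Across the 12402 genes, Pearson's r between the 2 sets of log2 fold changes was 0.854, while it averaged 0.448 in 100 simulations in which only the control arrays were shared and no gene had changed; genes are not independent replicates. The covariance was 0.162, against 0.00521 in those simulations, and 79.2% of genes had the same sign in both, against 64.8%. Both infections raised 1845 genes and lowered 1297, where calls independent of each other would give 486 and 309 and the simulations gave 0 and 0. The first leaves out the shared controls and the second the effects, so part of the excess may come from the shared controls. Of these 3142 shared genes, 74.9% had the larger change with CFT073. In the direct test of the strains 717 of them differed, and the change was larger with CFT073 in 672 and with 83972 in 45. The shared genes were chosen for passing with both strains, and the CFT073 estimates have larger standard errors. That choice may favour genes with a larger change with CFT073. Another 37 genes were called in both infections in opposite directions, and they included HSPA6, FOSB and the small nuclear RNA RN7SK, a regulator of transcription elongation. Both opposite calls were kept by 26, 20 and 28 of the 37 under quantile normalization, centring on probes above the floor and centring on reference genes, and by 16 to 29 when 1 array was left out. The second probe of HSPA6 fell with both strains (-1.82 and -0.60).

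**Figure D2:**
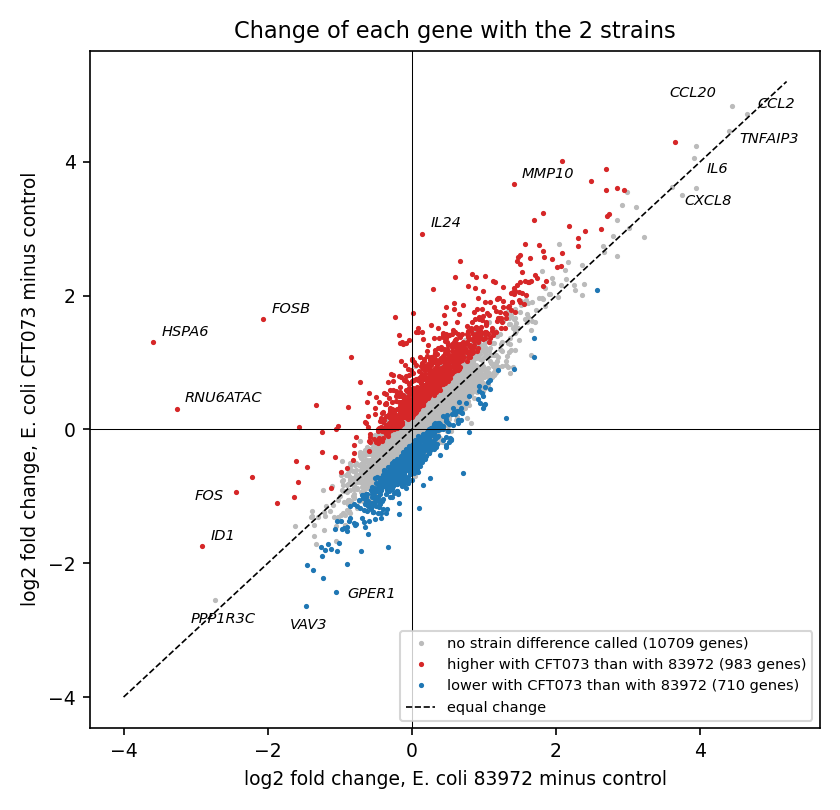
Log2 fold change of each of 12402 genes against control with 83972 (horizontal axis) and with CFT073 (vertical axis), in red for the 983 genes higher and blue for the 710 genes lower with CFT073 than with 83972, and a dashed line where both changes are equal. The genes lie along the diagonal with a Pearson's r of 0.854 across genes, and HSPA6, FOSB and RNU6ATAC lie far above it.

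The third comparison set CFT073 against 83972 directly, to find what separates the response to a virulent strain from that to an asymptomatic one. HSPA6 was 48.1-fold higher with CFT073 (log2 4.89 ± 0.33, adjusted p = 0.000311) and FOSB was 14.2-fold higher (3.72 ± 0.25, adjusted p = 0.000311). The HSPA6 intensities on the 83972 arrays were 21.0, 24.0 and 30.4, near the floor, so the size of its fold is uncertain. IL24, a cytokine of the IL10 family, was 12.6-fold higher (2.78 ± 0.09, adjusted p = 1.32e-05). Of the interferon-stimulated genes 29 of 35 were higher with CFT073 (camera adjusted p = 2.92e-19, adjusted p = 0.201 with an estimated correlation), and 19 of 30 G2/M genes were lower (3.94e-16, adjusted p = 0.155 with an estimated correlation). Several inflammatory genes that rose with both strains did not pass the test between them: the difference was 0.13 ± 0.14 for IL6 (adjusted p = 0.602), 0.07 ± 0.09 for TNFAIP3 (adjusted p = 0.701) and 0.09 ± 0.06 for NFKBIA (adjusted p = 0.416). In all, 983 genes were higher and 710 lower with CFT073, together 13.7% of those tested.

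RNU6ATAC was higher with CFT073 by 3.57 ± 0.16, with a mean intensity of 17.2 with 83972, near the floor. MMP10, a secreted protease of the matrix, was higher by 2.25 ± 0.19. The largest differences in the other direction were TSHZ1, a developmental transcription factor, at -1.43 ± 0.08, GPER1 at -1.38 ± 0.08, with -1.26 and -0.22 (adjusted p = 0.157) by its other probes, and FLRT3, a cell adhesion protein, at -1.35 ± 0.22. The FLRT3 call was lost without CFT073 array 2 and with the genes at the floor kept in the fit. HOXC6, a homeobox transcription factor, differed by -1.27 ± 0.07 and VAV3 by -1.17 ± 0.12. FOS differed by 1.50 ± 0.16 and EGR1 by 0.79 ± 0.10, both higher with CFT073, and MYC by -0.26 ± 0.12 (adjusted p = 0.224). The second probe of MYC showed -0.40 (adjusted p = 0.00873). ATF3 differed by 0.86 ± 0.21 (adjusted p = 0.032) and POLR2A by -0.37 ± 0.09 (adjusted p = 0.0338). The ATF3 call was lost without control array 2, any 83972 array or CFT073 array 1, and the POLR2A call without any single array other than control array 1. The second probe of HSPA6 was also higher with CFT073 than with 83972, by 1.22, but against control it showed -0.60 with CFT073 where the main probe showed 1.30. The CXCL8 difference was 0.02 ± 0.09 (adjusted p = 0.924), with intensities in the infected cells at 90.7% to 100% of the highest value on each array, and 0.05 by its second probe (adjusted p = 0.827).

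Interferon-stimulated genes were higher with CFT073 than with 83972 in 29 of 35 (32 adjusted over the list alone), with a median difference of 0.77 (camera adjusted p = 2.92e-19, adjusted p = 0.201 with an estimated correlation). Among them were OAS2, a sensor of double-stranded RNA, at 1.40, the antiviral GTPase MX1 at 1.31, the exonuclease ISG20 at 1.29 and the transcription factor IRF7 at 0.94. The 29 genes became 19 without 83972 array 1 and 16 without CFT073 array 2. NF-kB targets were higher in 17 of 29 (18 adjusted over the list alone), with PTGS2 at 1.20, the kinase MAP3K8 at 1.09 and NFKB1 at 0.65 (camera adjusted p = 4.75e-09, adjusted p = 0.155 with an estimated correlation). These 17 became 11 without 83972 array 1 or CFT073 array 2. Cytokines and chemokines were higher in 7 of 27 and lower in 1 (9 and 1 adjusted over the list alone), with the T cell chemokine CCL5 at 1.24 and IL15, a cytokine of natural killer cells, at 0.55 (camera adjusted p = 0.0059, adjusted p = 0.336 with an estimated correlation). That list's adjusted p was 0.26 when only genes above the 75th percentile of mean level were tested. Toll-like receptor signalling parts were higher in 4 of 27 (10 higher and 1 lower adjusted over the list alone), with IRAK2 at 0.49 and TLR5 at 0.46 (camera adjusted p = 0.00786, adjusted p = 0.155 with an estimated correlation, and 0.102 in the same subset of genes).

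G2/M genes were lower with CFT073 in 19 of 30 (26 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 3.94e-16, adjusted p = 0.155 with an estimated correlation). KIF11 differed by -0.72, KIF20A by -0.67 and ASPM, which organises spindle poles, by -0.69. G1/S and DNA replication genes were lower in 6 of 29 and higher in 1 (12 and 2 adjusted over the list alone), with ORC1 at -0.81 (camera adjusted p = 6.05e-05, adjusted p = 0.155 with an estimated correlation). The 6 became 3 without control array 3, 83972 array 1, 83972 array 3 or CFT073 array 2. Zinc finger genes of the ZNF family, most of them transcription factors, were lower in 39 of 322 and higher in 3 (37 and 3 adjusted over the list alone), with ZNF365 at -0.63 and ZNF385B at -0.64 (camera adjusted p = 5.28e-05, adjusted p = 0.155 with an estimated correlation). These 39 became 16, 20 and 22 without 83972 array 1, 2 or 3, and 19 and 18 without CFT073 array 1 or 2.

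Immediate early genes were higher with CFT073 in 17 of 33 and lower in 2 (22 and 2 adjusted over the list alone), among them FOSB, FOS, ID1 at 1.17, ID2 at 1.51 and the transcription factor KLF2 at 0.98 (camera adjusted p = 4.92e-08, adjusted p = 0.237 with an estimated correlation). The 17 became 11 without 83972 array 1 and 10 without 83972 array 3 or CFT073 array 1. TGF-beta targets were higher in 5 of 17, also when adjusted over the list alone, among them SNAI1, a repressor of E-cadherin, at 0.90, and THBS1, a matrix protein, at 0.85, beside ID1 and ID2 (camera adjusted p = 0.00523, adjusted p = 0.155 with an estimated correlation, and 0.363 among genes above the 75th percentile of mean level). FOS, ID1, ID2 and SNAI1 lay below control with both strains, so for them higher means a smaller fall with CFT073. Growth factors and EGFR ligands were higher in 5 of 15 (7 higher and 1 lower adjusted over the list alone), with HBEGF at 1.42 and BMP2 at 0.72 (camera adjusted p = 0.00786, adjusted p = 0.332 with an estimated correlation). The 5 became 2 without 83972 array 1, 83972 array 3 or CFT073 array 2. Unfolded protein and integrated stress response genes were higher in 7 of 27 (8 adjusted over the list alone), with DNAJB9, a chaperone of the endoplasmic reticulum, at 0.89 and MANF at 0.39 (camera adjusted p = 0.00128, adjusted p = 0.204 with an estimated correlation). The 7 became 4 without 83972 array 1, 83972 array 3 or CFT073 array 1. Metallothioneins, which bind zinc and copper, were higher in 3 of 5 (4 adjusted over the list alone), with MT1G at 1.06 and MT2A at 0.83 (camera adjusted p = 0.00131, adjusted p = 0.155 with an estimated correlation).

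Apoptosis regulators were higher in 7 of 28 and lower in 2 (8 and 2 adjusted over the list alone), with the survival factor BCL2L1 at 0.57, or 0.21 by its second probe (adjusted p = 0.426; camera adjusted p = 0.025, adjusted p = 0.195 with an estimated correlation). Without CFT073 array 2 the list's adjusted p was 0.11, and the 7 became 4 without control array 2, 3 without CFT073 array 1, and 2 without 83972 array 1, 83972 array 3 or CFT073 array 2. Hypoxia-inducible genes were higher in 10 of 28 and lower in 2, also when adjusted over the list alone, with ADM, a vasodilator peptide, at 0.68 (camera adjusted p = 0.0415, adjusted p = 0.325 with an estimated correlation). This call was lost without control array 2 or 3, 83972 array 1 or 3 or CFT073 array 1, and the count fell to between 3 and 6 without any single array other than control array 1. Antimicrobial and acute phase genes had a median of 0.24 over 11 genes, of which 1 passed, the protease inhibitor SERPINA3 at 0.65 (camera adjusted p = 0.0106, adjusted p = 0.155 with an estimated correlation). Without CFT073 array 2 the adjusted p was 0.106.

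**Figure D3:**
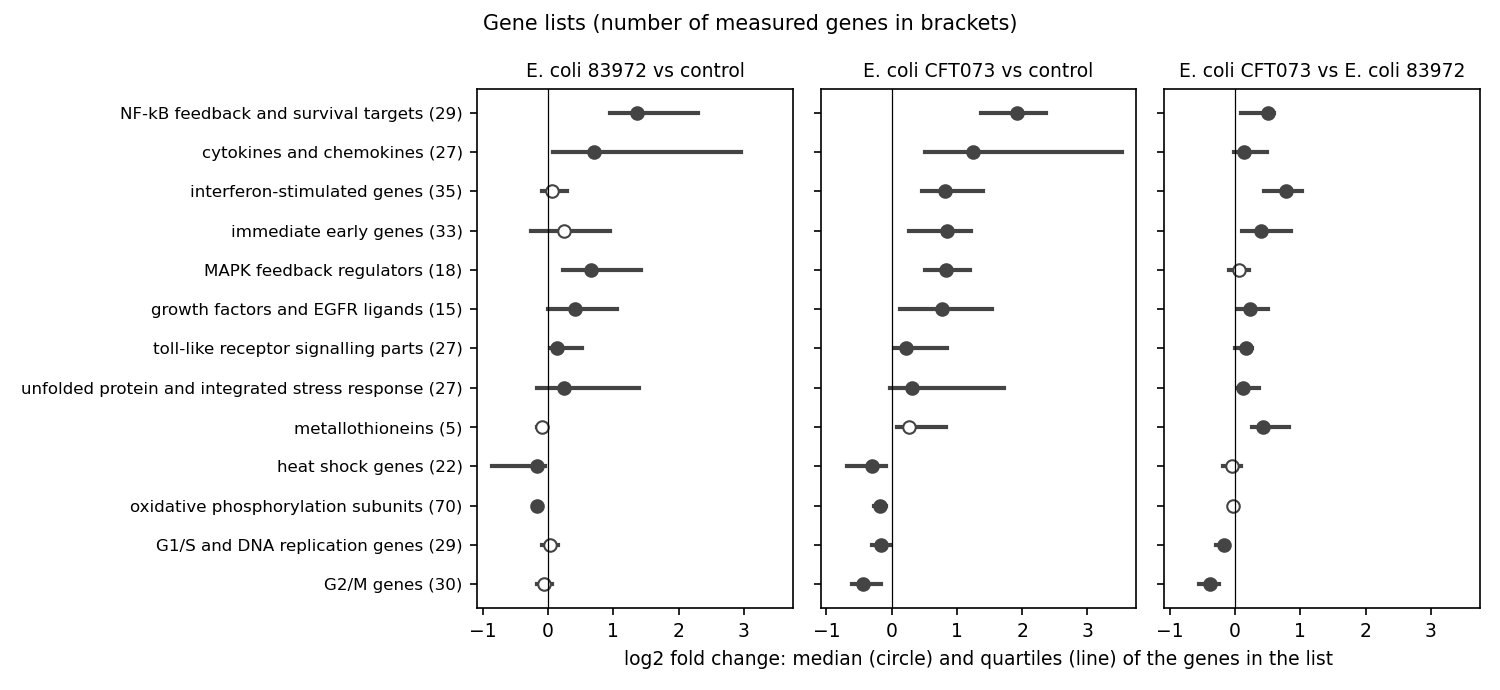
Median log2 fold change (circles) and quartiles (lines) of 13 gene lists in the 3 comparisons, with circles filled where the camera adjusted p is below 0.05. NF-kB targets lie highest in both comparisons with control, and between the strains interferon-stimulated genes lie highest of the 13 (median 0.77) and G2/M genes lowest (median -0.38).

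Over all genes tested, called or not, the arrays of the 2 strains did not overlap in 40.0%, where chance gives 20% for 3 arrays against 2. With the genes at the floor on every array kept in the fit, 524 were higher and 368 lower with CFT073, and the share of higher genes among calls, 58.1% as given here, was 46.1% with arrays centred on the probes above the floor.

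The lists of RNA polymerase subunits, general transcription factors, Mediator, ribosomal proteins, proteasome and reference genes did not pass the list test in any of the 3 comparisons with the settings used here. Some of them did with other settings. After quantile normalization the ribosomal proteins (camera adjusted p = 0.0319), proteasome subunits (0.0248) and reference genes (0.0319) passed with 83972, and RNA polymerase II subunits (0.046) and reference genes (0.0482) with CFT073. With arrays centred on probes above the floor the ribosomal proteins passed with 83972 (camera adjusted p = 0.0428) and CFT073 (0.0392). With 83972 they also passed by the mean of a gene's probes (0.0216), its most variable probe (0.0209) and with pseudocount 64 (0.0371). Ribosomal proteins also passed with 83972 without 83972 array 1 (0.0413) or 3 (0.00684) and without either CFT073 array (0.0416). They passed with CFT073 without CFT073 array 1 (0.00954). Of 11 RNA polymerase II subunits 2 fell with 83972, POLR2L at -0.30 and POLR2I at -0.24, and both calls were lost without control array 2 (camera adjusted p = 0.188). With CFT073 5 of these subunits fell, and 3 and 2 did without control array 3 and CFT073 array 2 (camera adjusted p = 0.116). Between the strains 2 were lower with CFT073 (camera adjusted p = 0.439). General transcription and elongation factors had 12 rises and 3 falls among 46 with 83972 (7 rises without control array 3), 11 and 6 with CFT073, and 3 genes higher and 3 lower between the strains (camera adjusted p = 0.161, 0.717 and 0.198). Mediator subunits had 6 rises and 2 falls among 27 with 83972, 10 and 3 with CFT073, and 2 and 2 between the strains (camera adjusted p = 0.253, 0.353 and 0.991). RNA polymerase I and III subunits had 9 rises and 2 falls among 21 with 83972 and 9 and 4 with CFT073 (camera adjusted p = 0.125 and 0.283, and 0.712 between the strains). Cytosolic ribosomal proteins had 3 rises and 11 falls among 74 with 83972 and 2 and 10 with CFT073 (camera adjusted p = 0.0744 and 0.129, and 0.968 between the strains). The 10 falls became 6, 5 and 4 without control array 2, control array 3 and CFT073 array 2. Of 33 proteasome subunits 1 fell with 83972, 2 rose and 4 fell with CFT073, and 1 was higher with CFT073 than with 83972 (camera adjusted p = 0.253, 0.584 and 0.712). Constitutive reference genes had 1 rise and 3 falls among 20 with 83972 and 5 falls with CFT073, or 2 without CFT073 array 2 (camera adjusted p = 0.134 and 0.197, and 0.797 between the strains).

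Several signalling and metabolic lists also did not pass with these settings. The p53 targets passed between the strains with arrays centred on probes above the floor (camera adjusted p = 0.0239) or on reference genes (0.0251), without control array 3 (0.046) and without CFT073 array 2 (0.0133). Cholesterol synthesis genes passed with 83972 without 83972 array 1 (0.042). Targets of p53 had 6 rises and 8 falls among 23 with 83972, 10 and 6 with CFT073, and 5 genes higher and 2 lower between the strains (camera adjusted p = 0.646, 0.54 and 0.0562), and the 5 became 1 without 83972 array 1. Among them TNFRSF10B, a death receptor, rose by 1.43 with 83972, with 0.36 (adjusted p = 0.0841) and 0.73 by its other probes, and SESN1 changed by -1.38. NRF2 targets had 4 rises and 1 fall among 18 with 83972, 4 and 2 with CFT073, and 1 gene lower between the strains (camera adjusted p = 0.672, 0.583 and 0.15). Cholesterol synthesis genes had 2 rises and 5 falls among 20 with 83972, 4 and 5 with CFT073 (2 falls without CFT073 array 2), and 3 genes higher between the strains, 1 without 83972 array 1 and none left without CFT073 array 1 (camera adjusted p = 0.0798, 0.438 and 0.341). Genes of neuropeptide and G protein-coupled receptor signalling had 7 rises and 3 falls among 21 with 83972, 9 and 1 with CFT073 (5 rises without control array 3), and 5 genes higher between the strains, 2 without 83972 array 1 (camera adjusted p = 0.399, 0.129 and 0.166). BDKRB1, a bradykinin receptor, rose by 1.95 with 83972. Negative regulators of cytokine receptors had 6 rises and 2 falls among 15 with 83972, 7 and 4 with CFT073, and 3 genes higher and 1 lower between the strains (camera adjusted p = 0.26, 0.309 and 0.79), and SOCS1, an inhibitor of interferon signalling, was 1.58 higher with CFT073 than with 83972.

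Junction genes had 5 rises and 2 falls among 14 with 83972 (3 rises without control array 2 or 3), 4 and 1 with CFT073, and 1 gene lower between the strains (camera adjusted p = 0.188, 0.197 and 0.712). CLDN1, a tight junction protein, rose by 2.84 with 83972 and 3.13 with CFT073. Epithelial and renal carcinoma line markers had 2 rises and 3 falls among 16 with 83972, 5 and 2 with CFT073 (2 rises without control array 3), and 2 genes higher between the strains (camera adjusted p = 0.906, 0.466 and 0.107). Leukocyte markers had 1 rise and 1 fall among 10 measured in each comparison with control (camera adjusted p = 0.806 and 0.906, and 0.797 between the strains). Endothelial and fibroblast markers had 1 rise and 2 falls among 8 with 83972, 1 and 1 with CFT073, and 1 gene higher between the strains (camera adjusted p = 0.261, 0.283 and 0.587).

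Some lists passed in 1 or 2 of the comparisons and not in the rest. With 83972 those that did not pass were, besides the interferon-stimulated and immediate early genes above, G2/M genes (5 rises and 3 falls among 30, camera adjusted p = 0.293, with 2 rises without control array 2), G1/S genes (3 and 4 among 29, 0.87), hypoxia-inducible genes (10 and 3 among 28, 0.26), apoptosis regulators (9 and 3 among 28, 0.188), antimicrobial genes (4 rises among 11, 0.0798), TGF-beta targets (4 and 6 among 17, 0.215), ZNF genes (77 and 33 among 322, 0.261, with 20 falls without control array 3) and metallothioneins (0.293). With CFT073 they were apoptosis regulators (10 and 4, camera adjusted p = 0.0634), metallothioneins (3 rises among 5, 0.114), histones (2 and 4 among 32, 0.235), TGF-beta targets (6 and 6, 0.906) and ZNF genes (64 and 70, 0.268, with 36 rises without CFT073 array 1 and 41 falls without CFT073 array 2). Between the strains they were oxidative phosphorylation subunits (1 lower among 70, camera adjusted p = 0.17), heat shock genes (3 higher and 4 lower among 22, 0.539), MAP kinase regulators (4 and 3 among 18, 0.545, with 1 higher without 83972 array 1 or 2 or either CFT073 array, 2 without control array 2, none of the 3 lower left without 83972 array 2 or CFT073 array 2, and 1 without control array 2 or 3 or 83972 array 1 or 3) and histones (2 higher, 0.0785). Some of these lists passed with other settings: immediate early genes with 83972 under all 3 other scalings (camera adjusted p = 0.0319, 0.0137 and 0.0474) and without control array 1 (0.047), and antimicrobial genes with 83972 after quantile normalization (0.0377). Apoptosis regulators passed with CFT073 under both centrings (camera adjusted p = 0.0273 and 0.0392), without control array 2 (0.0488) and without CFT073 array 1 (0.0478). Between the strains histones passed after quantile normalization (camera adjusted p = 0.0254) and without 83972 array 3 (0.0413), and oxidative phosphorylation subunits after quantile normalization (0.0392) and without CFT073 array 1 (0.00298). Small list counts moved easily: of the 89 counts of 1 to 4 genes over the 35 lists, 56 rose or fell by over 1.5 times without some single array. For a count of 1 or 2 the loss of 1 gene is enough, so this share says little about particular arrays. Among lists that did not pass, counts adjusted over the list alone differed from these with 83972 for p53 targets (7 rises and 10 falls), ZNF genes (79 and 34), ribosomal proteins (3 and 10), hypoxia-inducible genes (10 and 4), RNA polymerase I and III subunits (9 and 3), cholesterol synthesis genes (2 and 6), antimicrobial genes (4 and 1), G1/S genes (1 and 3), reference genes (1 and 2), and proteasome subunits and leukocyte markers, which lost their 1 fall. They differed with CFT073 for ZNF genes (64 and 73), apoptosis regulators (11 and 4), RNA polymerase I and III subunits (10 and 4), Mediator subunits (10 and 4), general transcription factors (10 and 5), G protein-coupled receptor signalling (9 and 2), ribosomal proteins (1 and 4), proteasome subunits (2 and 1), histones (1 and 1) and leukocyte markers, which lost their 1 fall. Between the strains they differed for p53 targets (9 higher and 2 lower), MAP kinase regulators (5 and 3), heat shock genes (3 and 5), negative regulators of cytokine receptors (5 and 2), Mediator subunits (3 and 2), G protein-coupled receptor signalling (7 higher), cholesterol synthesis genes (4 higher), epithelial markers (3 and 1) and NRF2 targets, which lost their 1 lower gene.

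The median, the mean and the direction of the list test differed in sign with 83972 for p53 targets, NRF2 targets, G protein-coupled receptor signalling, G1/S genes and epithelial markers. They differed with CFT073 for NRF2 targets, TGF-beta targets and leukocyte markers, and between the strains for heat shock genes, G protein-coupled receptor signalling and negative regulators of cytokine receptors. With genes at the floor in one group entered at the bound of their fold, the largest move of a list median was 0.0728, for antimicrobial genes with 83972. Another scaling of the arrays turned the sign of the median of Mediator subunits in all 3 comparisons. It did so with 83972 for ZNF genes, G1/S genes and epithelial markers, with CFT073 for general transcription factors, p53 targets and TGF-beta targets, and between the strains for ribosomal proteins, proteasome subunits, cholesterol synthesis genes and leukocyte markers.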

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

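The tests of the interferon pattern, of RNA without a poly(A) tail and of other products of RNA polymerase III were chosen only after the result was seen. The other tests were recorded as set before their own results were seen. Those of the genes changed in opposite directions and of the scaling of the small RNAs address patterns already found in the data. They also use centrings that were chosen after the values were seen.

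The 2 strains moved 37 genes in opposite directions against control, and all 37 also differed in the direct test of the strains, 22 of them higher with CFT073. They were picked because the infections differed in them: HSPA6, a heat-induced chaperone, by 4.89 on the log2 scale, the AP-1 subunit FOSB by 3.72 and the elongation regulator RN7SK by 1.93. The strain difference was kept by 37 genes under each of 3 other scalings, and by at least 36 whichever array was left out. Those scalings changed the calls of other genes (983 higher and 710 lower became 941 and 919, 753 and 881, and 710 and 752). Genes selected for opposite calls against control were nearly certain to differ between the strains. Keeping that difference therefore cannot decide on array scaling or a single array as its source. In the 7 genes with another probe above the floor, 100% of the 9 other probes had the same strain direction, although against control those of HSPA6 (-1.82 and -0.60) and ALAD and 1 of PLPP1 went the same way with both strains, and for the remaining genes a probe effect stays open. Opposite calls against control depended on the scaling and on single arrays, with 26, 20 and 28 of the 37 keeping both under quantile normalization, centring on probes above the floor and centring on reference genes, and 16 to 29 with 1 array left out; a biological difference between the strains is a hypothesis that was not tested further.

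Interferon-stimulated genes were higher with CFT073 than with 83972, by a median of 0.77. Under the 3 other scalings the lowest median was 0.73. Those scalings shifted the median gene between the strains by only -0.012, -0.041 and -0.037, too little to test a difference of this size. Over the 8 left-out arrays the lowest median was 0.53, without CFT073 array 2, so no single array accounts for the whole difference. The number of genes called did depend on single arrays, with 16 of 35 without CFT073 array 2 and 19 without 83972 array 1. IFNB1, the gene of interferon beta, was also higher with CFT073, by 0.88 ± 0.14 (n = 2 against 3, adjusted p = 0.00641 with limma). More interferon transcript with CFT073 is thus a candidate explanation, found and tested on the same data. With 83972, however, IFNB1 was at least 13.0-fold above control. Of the 35 interferon-stimulated genes, 8 rose and 3 fell with 83972, with a median of 0.06. The IFNB1 difference alone therefore cannot decide on this explanation. IFNL1, another interferon gene, was above the floor with CFT073 only.

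RNU6ATAC, RN7SK and RPPH1, small RNAs made by RNA polymerase III, were lower with 83972 than with CFT073, by 3.57, 1.93 and 1.70. The smallest of these differences under 3 other scalings was 1.66. Those scalings shifted the median gene between the strains by only -0.012, -0.041 and -0.037, too little to test differences of this size. RNU6ATAC was near the floor with 83972. A loss of RNA without a poly(A) tail in labelling would lower the small nucleolar RNAs as well, if their probes read such RNA. Whether they do was not tested. The 26 above the floor on all arrays had a median strain difference of -0.18 (quartiles -0.28 and 0.00). A loss of such RNA, or of part of it, stays open. The ribosomal RNA RNA28SN5 was also 0.76 higher with CFT073 (adjusted p = 0.0157 with limma). A shift of all products of the polymerase would raise RN7SL1, BCYRN1 and SNAR-A1 with CFT073, and the largest of their differences was 0.21. What sets the 3 RNAs apart stays open, and no biological explanation beyond the strain itself was tested.

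Probes without exactly 1 gene symbol were not part of the comparisons above. Of the 5170 above the floor, 558 were called between 83972 and control, 687 between CFT073 and control and 122 between the strains.

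For the genes called between 83972 and control, 1 of the 10 splits of the 6 arrays, the real one, gave as many as its 3922. The highest of the other splits gave 0 with limma, with 192 to 485 genes at an unadjusted p under 0.05 across the other splits, and 10 splits are too few for a share under 0.05. Each other split also mixes control and 83972 arrays, so the change between them widens the spread within its groups. Few calls in those splits were thus nearly fixed in advance, and they lend no weight to the real split.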

How the results depend on the processing

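The alternatives that keep the genes at the floor, test only genes above it on all arrays, raise values below it, or centre arrays on probes above the floor or on reference genes were chosen only after the values were seen. Quantile normalization gave 2700 falls with 83972, and the cause was not tested. Testing only the 4713 genes above the 75th percentile of mean level left fewer genes to call: 1368 rises and 838 falls with 83972, 1548 and 1099 with CFT073, 600 and 439 between the strains, with r = 0.883 between the infections. A stricter threshold of 0.01 left 877 falls with 83972, 1360 falls with CFT073, and 404 higher and 255 lower between the strains. Asking also for a log2 change of 0.5 left 968 rises and 378 falls, 1493 and 787, and 416 and 199. Keeping the genes at the floor in the fit left 524 and 368 between the strains, and the cause was not tested.

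Without 1 array, with a lone CFT073 array assumed to vary like the other groups, rises with 83972 ran from 1720 to 2206 and falls from 1179 to 1811, rises with CFT073 from 2200 to 2681 and falls from 1688 to 2152. Between the strains 515 to 862 were higher and 407 to 607 lower. Those 983 and 710 became 515 and 407 without 83972 array 1, 717 and 458 without array 2, 616 and 439 without array 3, 722 and 410 without CFT073 array 1, and 610 and 454 without CFT073 array 2, with fewer arrays to test. The r between the infections ran from 0.832, without CFT073 array 2, to 0.859. With the replicate number as a fixed block the counts were 2059 and 1552, 2478 and 1865, and 698 and 494; arrays of one number did not pair, with a consensus correlation of the block of -0.036 and correlations of -0.01, 0.016 and 0.131 between control and 83972 arrays of the same number. All other counts and r stayed within 1.5 times, or within the spread of r, in the alternatives run.

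ATP5PF, -0.24 with 83972, was 0.32 (adjusted p = 0.126) by its most variable probe, and the cause was not tested. The p53 targets with 83972, with a median of -0.13, were called upward by fry (adjusted p = 0.0352), and the cause was not tested. Of the 105 list results, 38 lost their call with an estimated correlation, and 35 gained one with fry. Calls were lost by 6 list results with genes above the 75th percentile and by 5 at the threshold of 0.01. With the floor genes kept 2 were lost, as were 2 in the upper 50% of genes. Pseudocount 64, the mean of a gene's probes, the most variable probe and genes above the floor on all arrays lost 1 each. Calls were also gained by 9 list results after quantile normalization, 5 and 3 with arrays centred on probes above the floor and on reference genes, 7 with the genes at the floor kept in the fit, 4 with genes above the 75th percentile, 2 each with genes above the floor on all arrays and with the fixed block, 1 each with pseudocount 64, the upper 50% of genes, the mean of a gene's probes and the most variable probe, and 0 to 4 with 1 array left out. With the floor genes kept, those were immediate early genes, general transcription factors, ribosomal proteins, cholesterol synthesis genes and reference genes with 83972, apoptosis regulators with CFT073 and p53 targets between the strains. Above the 75th percentile the ribosomal proteins passed with both strains, and immediate early genes and ZNF genes with 83972 (adjusted p = 0.0139 and 0.000225); the causes were not tested. Centring on the median of all probes changes nothing, since each median is the floor, and the alternative for values on a log2 scale had no use for linear values. Signal over background limits the genes near the floor, and a fold is a bound where the lower group was at the floor on all its arrays.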

Other observations

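The tests of interferon transcripts and of POLR2A were chosen only after the result was seen. The test of other bone morphogenetic protein targets was recorded as set before its own result was seen, for a fall already found in the data.

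Both infections raised the interferon beta gene IFNB1, which was at the floor in all control arrays: it was at least 13.0-fold higher with 83972 and at least 24.9-fold higher with CFT073. IFNL1, a type III interferon, was not above the floor in control or 83972 arrays and was at least 3.33-fold higher with CFT073, with a strain difference of 1.05 ± 0.09 (n = 2 against 3, adjusted p = 0.000718 with limma). Among RNAs that do not code for proteins, RNU6ATAC of the minor spliceosome changed by -3.26 with 83972 and showed 0.31 ± 0.16 with CFT073 (adjusted p = 0.161). RN7SK, which holds back transcription elongation, changed by -0.85 ± 0.10 with 83972 and by 1.08 ± 0.11 with CFT073, and its second probe showed -1.81 and 1.40. RPPH1, the RNA of ribonuclease P, changed by -1.33 ± 0.17 with 83972 and showed 0.37 with CFT073 (adjusted p = 0.173). RN7SL1, the RNA of the signal recognition particle, rose with both strains, by 0.59 and 0.51. These genes were chosen after their values were seen.

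A hypothesis that RNA polymerase II subunit transcripts are lower with 83972 than with CFT073 was tested on POLR2A, which differed by -0.37, lower with CFT073, the opposite of what the hypothesis needs. That call was lost without any single array other than control array 1.

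ID1, ID2, ID3, SMAD6, BAMBI and SNAI1, targets of bone morphogenetic proteins, fell with 83972, with log2 fold changes of -2.91, -2.22, -0.67, -0.57, -0.57 and -1.46, while BMP2 rose by 0.94. A fall of all such targets was tested on 6 others, 5 of them measured. Of these 20% were called lower, SMAD9 at -0.25 ± 0.07 (adjusted p = 0.0275), and HEY1 rose by 0.31 ± 0.07 (adjusted p = 0.0137). MSX1, well above the floor, showed -0.12 (adjusted p = 0.204). Not all targets therefore fell with 83972. ATOH8 and MSX2 had mean intensities of only 36.1 and 26.1 in control cells, near the floor, where a fall is hard to see. So 5 genes cannot decide how wide the fall with 83972 was. With CFT073 the first 6 genes also fell, at -1.74, -0.70, -0.68, -0.51, -0.54 and -0.56, and 3 of the 5 others were called lower, SMAD9 at -0.95 and ATOH8 at -0.69 and MSX2 at -0.48, the last 2 near the floor, while HEY1 rose by 0.85, so a wider fall with CFT073 stays open.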
